A study of Rana pirica with 9 samples.

How the data were processed

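Gene expression was measured in brains of tadpoles of Rana pirica, a brown frog, on one-colour Affymetrix Xenopus GeneChip arrays, which were designed for the clawed frog Xenopus. RNA of one frog was thus hybridized to probes for another. Per the labels, 6 samples came from tadpoles kept without predators and 3 from tadpoles kept with salamander larvae, all for 8 days, and each sample pooled 10 brains. The labels call the samples of a group biological replicates and number them 1 to 6 and 1 to 3. Groups and replicate numbers were taken from the sample titles.

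Per the submitters' processing notes, signals were computed with MAS5, the Affymetrix signal algorithm, whose version is not given in the sources used here. The deposited table holds log2 values with positive and negative signs for 15611 probe sets on 9 arrays, and 0 columns of other samples. In each row the median of the 6 control arrays was 0, with a largest departure of 9.5e-07, so that the authors' log2 signals had been centred on the control median of each probe set. No label states the logarithm or the centring. Both were read from the values, and base 2 from the rounding steps of the numbers. The absolute signal of a probe set is therefore unknown, and so is how the arrays were scaled to each other before centring. Array medians lay between -0.01 and 0.01. Subtracting a constant per probe set changes no difference between groups, but it removes the level on which a filter, a pseudocount and an intensity trend would rest.

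The design fixed before the data were examined had assumed signals with a level. It named limma with an intensity trend, a filter that kept the brighter probe sets by mean signal, and the brightest probe set of each gene. These could not be computed. In their place, before any fit was made, limma's lmFit and eBayes were used without a trend on all 15491 probe sets other than the 120 Affymetrix control probe sets, and a gene's value was the mean of its probe sets. These replacements were among the alternatives fixed in advance. The contrast was salamander minus control over 9 arrays. P-values were adjusted by the Benjamini-Hochberg method and called at an adjusted p under 0.05. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.

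A partial measure of level was recovered from the rounding. The values carry single-precision steps, and a step too fine for a logarithm of 8 or more marks a signal below 256. The mark can come from the array's own signal or from the control median subtracted from it. A signal below 256 can also fall on a coarser step and stay unmarked. Marked values, called weak below, are thus no full count of weak signals. Probe sets with at most 1 marked value among the 9 arrays, 7349 in number, are called bright below. This set was defined after the data were seen. On simulated rows the rule marked as bright 100.0% of those with a mean log2 level over 8.5, and 1.88% of those under 7.5. Those rows varied less between arrays than most real probe sets, whose replicate SD had a median of 0.96. The shares thus need not hold for the real probe sets.

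Names came from the platform annotation supplied with the values, and none was given to a probe set with several symbols. The annotation listed 9499 probe sets, of which 9304 had 1 symbol and 195 several; 6187 tested probe sets were unnamed here. Symbols were put in lower case and the endings that mark homeologs were removed, which left 6485 genes, 2022 of them with more than 1 probe set.

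Genes were named by a rule fixed in advance. It took the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, filled to 5 per side by smallest p where fewer passed. It also took, for each list described with examples, up to 4 passing members or otherwise the 2 with the smallest p, and 16 genes of the stress axis, the pituitary and the brain wherever measured. Lists described with examples were chosen after the data were seen. Features named outside the rule are said to be so.

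The 34 gene lists, also fixed in advance, covered the stress axis, neuropeptides and secretory granules, pituitary hormones, GABA and glycine signalling, glutamate signalling, monoamine and acetylcholine signalling, voltage-gated ion channels, synaptic vesicles and exocytosis, immediate early genes, heat shock and protein folding, the thyroid hormone response, the cell cycle, neural progenitors, ribosomal proteins, oxidative phosphorylation, glycolysis, cholesterol and fatty acid synthesis, myelin, astroglia and ependyma, microglia and leukocytes, antigen presentation and interferon, complement and liver plasma proteins, erythrocytes, endothelium, skeletal muscle, skin and keratins, retina and lens, connective tissue matrix, insulin and growth factor signalling, the circadian clock, oxidative stress, cytoskeleton and axon, transcription and splicing, and proteasome and ubiquitin. They were tested with camera at a preset inter-gene correlation of 0.01, beside an estimated correlation and fry, and adjusted over the 34 lists. Lists needed at least 5 genes.

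Array pairs were compared for duplicates. No pair shared more than 1 identical value, and the SD of the difference between 2 arrays lay between 1.39 and 1.48, so all 9 were kept as separate samples. Probe sets for RNAs added during labelling (poly-A spike-ins, 24 probe sets) and at hybridization (18 probe sets) were averaged per array to look for technical batches.

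The fits were tested on simulated data, 20 tables with the SD of each real feature and 200 changed features. The noise was normal and independent between features, and the changes in each table mixed all sizes given next. With fewer changed features, or with longer tails, the shares called could be lower. Over all probe sets, 0.5% of 2-fold changes, 14.4% of 4-fold, 44.0% of 8-fold and 68.6% of 16-fold changes were called. Over genes the shares were 1.6%, 37.2%, 66.4% and 87.1%. A simulated shift of 0.5 on the log2 scale in the 27 synaptic vesicle genes was called by camera in 95.0% of tables, and one of 0.25 in 15.0%. The number of arrays limits the precision.

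Alternatives comprised quantile normalization, equal array medians, array weights, robust eBayes, other control subsets, a replicate block, a looser threshold, other list tests and leaving out each array. Those added after the data were seen were the bright probe sets, the poly-A spike-in level as a term, each spike-in level by itself, quantile normalization after centring each probe set on the mean of all 9 arrays, and an unmoderated linear model. The median replicate SD of each list was compared with 2000 random lists. They were matched on the number of probe sets per gene and of weak values, meaning values marked by the rounding, per probe set. This comparison too was chosen after the data were seen.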

Results

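Brains of Rana pirica tadpoles that had not yet grown hind limbs were profiled after 8 days with salamander larvae, which prey on tadpoles, or without them. The control group had 6 arrays and the salamander group 3, and each array carried RNA pooled from 10 brains. Values are log2 MAS5 signals relative to the median control array, as deposited. They give differences between groups but no absolute level of any gene, and the number of arrays limits their precision. The comparison asks which brain transcripts differed in tadpoles kept with salamander larvae.

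Between tadpoles kept with salamander larvae and controls, no gene passed the test over all genes and no gene list passed. The groups overlapped in every entry fixed for reporting in advance, among them the hormone precursors pomc and prl.1, the glucocorticoid receptor nr3c1, myelin basic protein mbp and haemoglobin alpha hba1. Overlap is the usual outcome here and tells little about these entries. Of all 6485 genes, the groups did not overlap in 142, or 2.19%, where chance gives 2.38%. The largest difference by p-value was in a probe set without a gene name here, which was 3.38 higher on the log2 scale in the salamander group (SE 0.43), or 10.4-fold. All 3 salamander arrays, at 3.28 ± 0.38 (SD, n = 3), lay above all 6 control arrays, at -0.10 ± 0.40 (SD, n = 6). Its adjusted p in limma was 0.0846, short of the threshold of 0.05. By the rounding, its values were marked as weak, under the level that defines bright probe sets, on 4 of the 6 control arrays and 0 salamander arrays. Weak signals can escape the mark, so further arrays may be weak too. The fold thus rests on weak signals in at least part of the controls.

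Of 15491 probe sets, limma called 0 at an adjusted p under 0.05 and 1 under 0.10. An unadjusted p under 0.05 was reached by 798 probe sets, 5.15% of those tested, against 774.6 expected by chance, with 329 higher and 469 lower in the salamander group. A linear model without moderation gave 0 calls and 719 probe sets at an unadjusted p under 0.05. At the level of 6485 genes, 0 passed, the smallest adjusted p was 0.265, and 312 had an unadjusted p under 0.05, of which 135 were higher and 177 lower. The groups did not overlap in 361 probe sets, or 2.33%, where chance gives 2.38%. The SD between replicate arrays had a median of 0.96 on the log2 scale per probe set and 0.82 per gene. For 516 genes, 7.96% of all, the 95% confidence interval excluded a difference of 2-fold either way, and for 4493 genes, or 69.3%, it excluded one of 4-fold. With 1 salamander array left out, the number with 2-fold excluded was 71 to 80, and with 1 control left out 297 to 363. Different probe sets of 1 gene barely went together: in 4219 pairs their differences between groups had the same sign in 49.9% and their deviations from group means correlated at 0.0088 on average, against 49.1% and 0.0050 in random pairs. Whether a probe set reports the frog transcript of the gene it is named for was therefore not shown, nor whether the deposited values are those computed from the arrays or were altered before deposit, and this limits what each named gene's difference, each interval and each list mean given here says about that gene.

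Among genes fixed for reporting in advance, 14 entries were measured and the groups overlapped in all 14. Over all genes they did not overlap in only 2.19%. The gene pomc, whose product is cut into corticotropin and melanotropin, had a difference of -0.65 (95% confidence interval -1.99 to 0.69). Its 2 probe sets disagreed, at 0.60 (SE 0.75) for one with mostly weak signals and -1.90 (SE 0.66) for one with strong signals. The glucocorticoid receptor gene nr3c1 differed by 0.02 (interval -0.90 to 0.94), a mean of probe sets at -0.01 (SE 0.44), 0.77 (SE 0.48) and -0.70 (SE 0.63). The feeding peptide gene npy had a difference of -0.38 (interval -1.71 to 0.95), with probe sets at 0.06 and -0.82, and somatostatin, sst.1, one of -0.23 (interval -1.39 to 0.92). Of the pituitary hormone genes, prolactin, prl.1, stood at 0.47 (interval -1.04 to 1.97), and the growth hormone genes gh1 and gh2 at 0.31 and -0.02, gh1 with probe sets at 0.86, 0.49 and -0.41, and gh2 turning to 0.0088 after quantile normalization of the values as deposited. The shared subunit of the glycoprotein hormones, cga, was at -0.19 (interval -1.19 to 0.81), with probe sets at 0.03 and -0.41. The activity-induced transcription factor egr1 differed by 0.04 (interval -0.81 to 0.88). Of the entries for the enzyme that makes GABA, gad1.1 was at -0.23 (interval -2.14 to 1.68) and gad1.2 at -0.96 (interval -2.76 to 0.83), the latter with control array 1 at 3.75 and the other controls at or below 0.38. Transthyretin, ttr, a carrier of thyroid hormone, had the highest difference of these entries, 0.90 (interval -0.32 to 2.12). Myelin basic protein, mbp, was at -0.55 (interval -1.68 to 0.57) and haemoglobin alpha, hba1, at -0.31 (interval -1.12 to 0.49). With 1 array left out, only ttr of these 14 stayed within 1.5 times its difference, at 0.65 to 1.24. The sign turned in 6, namely cga, egr1, gad1.1, gh2, nr3c1 and sst.1, and the other 7 moved further without turning. Among the latter, pomc ran from -1.33 without salamander array 2 to -0.06 without salamander array 1, prl.1 from 0.013 without salamander array 1 to 0.87 without salamander array 3, gad1.2 from -1.19 without control array 2 to -0.33 without control array 1, npy from -0.76 to -0.16, mbp from -0.99 to -0.31, gh1 from 0.19 to 0.45 and hba1 from -0.42 to -0.20. The genes crh, tshb, penk and fos were not matched to a probe set with 1 symbol and were not analysed here.

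The genes with the smallest p-values on each side are given as values, since none passed. On the higher side they were degs3 at 2.31 (SE 0.42), prodh, which breaks down proline in mitochondria, at 2.41 (SE 0.49), the proteoglycan kinase fam20b at 1.94 (SE 0.41), the Wnt receptor fzd2 at 1.92 (SE 0.44) and the mitochondrial carrier slc25a32 at 2.17 (SE 0.51). On the lower side stood cwf19l1 at -2.13 (SE 0.37), with control array 5 at -0.79 apart from the other controls, the Golgi tether uso1 at -2.38 (SE 0.43), the death receptor adaptor fadd at -2.12 (SE 0.39), kin at -1.89 (SE 0.37) and the matrix proteoglycan lum at -1.81 (SE 0.39). In each of these 10 genes the 3 salamander arrays lay outside the range of the controls. Picking genes for small p-values in the same arrays favours this, so it is no further evidence of a difference. Adjusted p-values in limma ran from 0.265 to 0.550. Values were marked as weak on 8 of the 9 arrays for prodh, on 4 for degs3 and on 3 for fam20b, slc25a32 and uso1. They were so marked on 2 for fzd2 and cwf19l1, and on at most 1 for fadd, kin and lum. Because weak signals can escape the mark, these counts are no upper limits on the weak arrays. Of the 52 genes named by rule, 9 had at least 4 weak values per probe set: besides prodh and degs3, these were amph with 7, ctss, dusp6, chga and prl.1 with 4 each, gh1 with 4.7 and tsc22d3 with 4.5.

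**Figure D1:**
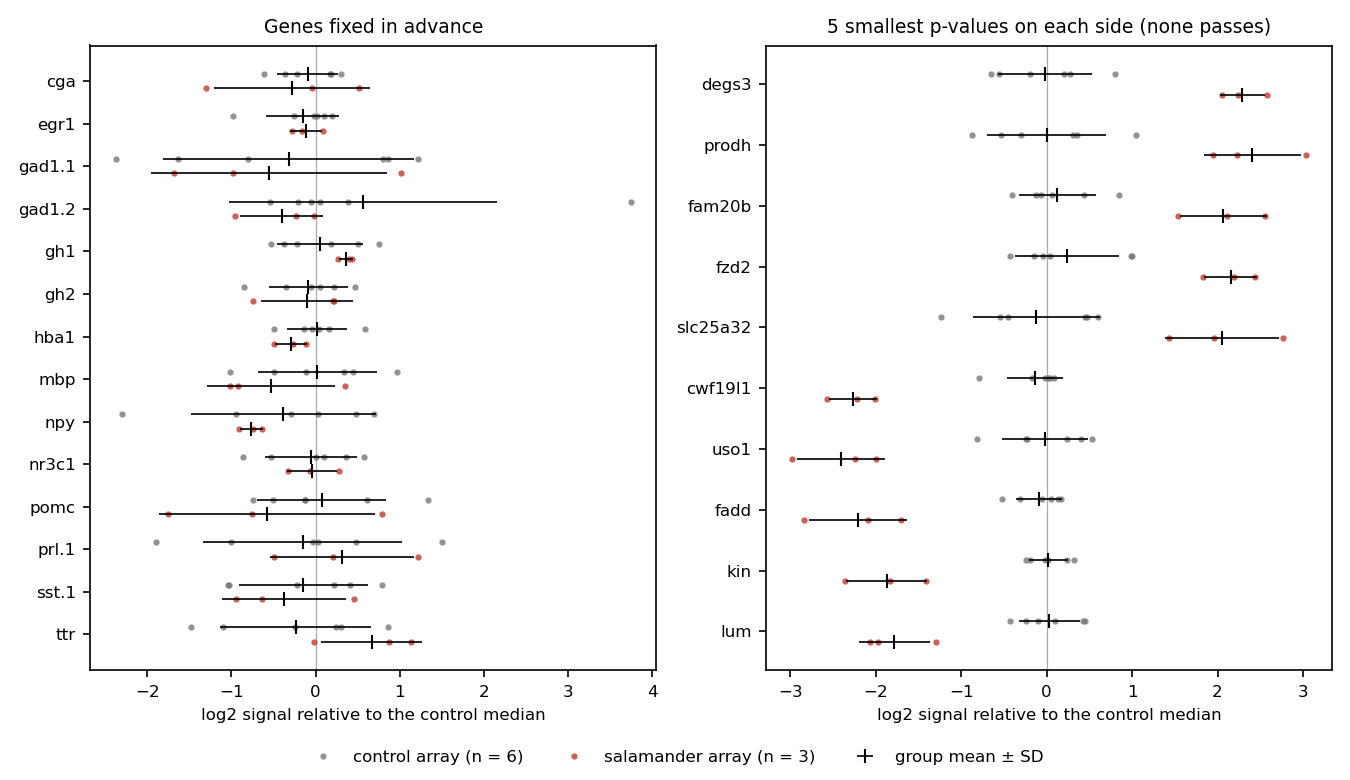
Log2 signal relative to the control median (horizontal axis) for the 14 entries fixed in advance (left) and the 10 genes with the smallest p-values (right), with each control array in grey (n = 6), each salamander array in red (n = 3), and vertical ticks and bars for the group mean and SD. The groups overlap in every entry on the left, as they do in most genes. On the right all salamander arrays lie outside the controls, which picking genes for small p-values favours, and no gene passes the threshold.

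Of the 34 gene lists, camera called 0 at an adjusted p under 0.05. It gave 3 an unadjusted p under 0.05, where 1.7 are expected by chance, each with an adjusted p of 0.349. With an estimated correlation 1 list had an unadjusted p under 0.05, with 0 calls and a smallest adjusted p of 0.674. Fry, which tests whether a list's genes move one way on balance, gave 3 at an unadjusted p under 0.05 and 0 calls, with a smallest adjusted p of 0.173; its test for change in either direction gave 2 and 0. No list held a gene that passed over all genes tested. Adjusted over the list alone, 31 lists held 0 passing genes and 3 held 1. By chance about 1.7 lists would hold one, and 2 of these 3 share the same gene, ctss, described below.

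Synaptic vesicle and exocytosis genes had a mean difference of 0.29, with 18 of 27 positive, and a camera p of 0.0279 (p = 0.0430 with an estimated correlation). The vesicle chaperone dnajc5 was at 1.79 (SE 0.54) and the endocytosis protein gene amph at 1.22 (SE 0.65). Circadian clock genes had a mean of 0.44, with 11 of 13 positive, and a camera p of 0.0290 (p = 0.0643 with an estimated correlation). The clock repressor cry1 was at 1.35 (SE 0.74) and noct at 1.09 (SE 0.66). Cytoskeleton and axon genes had a mean of 0.22, with 33 of 49 positive, and a camera p of 0.0308 (p = 0.161 with an estimated correlation). The neuronal intermediate filament gene ina was at 2.68 (SE 0.69) and the dynactin subunit dctn1 at 1.73 (SE 0.65). Within technical levels described below, the cytoskeleton mean was -0.03 on the arrays with high spike-ins and 0.62 on those with low ones, the latter resting on salamander array 3 alone. Without that array the cytoskeleton mean was 0.07 and 0 lists had a camera p under 0.05, and without salamander array 2 the mean was 0.35 and there was 1 such list.

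In the stress axis list, 4 of 11 genes were positive, with a mean of -0.35 and an adjusted p of 0.635 in limma's camera test. Within the spike-in levels its mean was 0.02 on the high arrays and -0.84 on the low ones, the latter again resting on salamander array 3 alone. Its smallest p-values belonged to the corticosteroid-responsive kinase gene sgk1, at -1.97 (SE 0.78), and tsc22d3, also induced by glucocorticoids, at -0.66 (SE 0.56). The probe sets of tsc22d3 disagreed, at -1.39 (SE 0.70) and 0.08 (SE 0.85). Of the neuropeptide and secretory granule genes, 8 of 23 were positive (adjusted p = 0.773), with the granule protein chga at -0.99 (SE 0.57) and the receptor gene trhr at -0.78 (SE 0.69). The pituitary list had 5 positive genes of 10 (adjusted p = 0.684), including the transcription factors pitx1, at 1.27 (SE 0.38), and hesx1, at -0.89 (SE 0.69). Immediate early genes, which neurons induce on activity, had 9 positive of 26 (adjusted p = 0.635), with cebpd at 1.27 (SE 0.53) and dusp6 at -0.78 (SE 0.45). Heat shock and folding genes had 23 of 43 positive (adjusted p = 0.810), although the chaperone genes hspa8 and hsph1 stood at -1.55 (SE 0.45) and -1.43 (SE 0.47), the latter with control array 2 at -1.11 apart from the rest. The thyroid hormone response list had 8 of 23 positive (adjusted p = 0.635), with the metalloproteinase mmp14 at -0.73 (SE 0.41) and the coactivator ncoa2 at -1.02 (SE 0.59). Of 90 cell cycle genes, 38 were positive (adjusted p = 0.635), and the list's mean on control array 3, -0.28, lay apart from the other controls. The proliferation marker mki67 was at -1.34 (SE 0.43) and the cyclin ccna1 at -1.04 (SE 0.44).

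Markers of glia, blood and connective tissue also gave no call as lists. Myelin genes had 5 positive of 12 (adjusted p = 0.635), with pmp22 at -1.33 (SE 0.41) and pmp2 at -1.19 (SE 0.53). The lysosomal protease gene ctss was at 2.39 (SE 0.61), with all 3 salamander arrays above all controls, and it passed when adjusted over the list alone, at 0.0397 among 17 microglia and leukocyte genes and at 0.0210 among 9 antigen presentation genes. Over all genes its adjusted p in limma was 0.672. The lists themselves had 9 and 5 positive genes, with adjusted p-values of 0.773 and 0.635, and the antigen presentation mean was 0.44 over all arrays, 0.71 on the high spike-in arrays and 0.08 on the low ones. The complement gene c1qc was at 0.52 (SE 0.42) and the immunoproteasome gene psmb8 at 1.27 (SE 0.78). Erythrocyte genes had 8 of 23 positive (adjusted p = 0.810), with the red cell anion exchanger slc4a1 at -1.90 (SE 0.54) and hba3 at -1.58 (SE 0.77). In connective tissue matrix, 17 of 33 were positive (adjusted p = 0.906). There lum passed when adjusted over the list alone, at 0.0186, and the collagen gene col6a1 was at -1.37 (SE 0.68), with control array 4 at -2.67.

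Of the 38 genes named outside the entries fixed in advance, 9 moved by over 1.5 times with 1 array left out and 0 turned sign. These 38 were picked for small p-values in the same arrays, so a turn was unlikely and its absence shows no stability. The granule protein gene chga ran from -1.44 without salamander array 3 to -0.35 without salamander array 1, hesx1 from -1.70 to -0.38, trhr from -1.21 to -0.31, ncoa2 from -1.66 to -0.53, noct from 0.63 to 1.49, mmp14 from -1.12 to -0.44, ccna1 from -1.32 to -0.63, tsc22d3 from -0.97 to -0.42 and col6a1 from -1.89 to -0.90.

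The other lists gave no call either. Positive genes numbered 6 of 13 for GABA and glycine signalling (adjusted p = 0.906), 6 of 10 for glutamate signalling (adjusted p = 0.906), 2 of 10 for monoamine and acetylcholine signalling (adjusted p = 0.635), 5 of 16 for voltage-gated ion channels (adjusted p = 0.635), 31 of 62 for neural progenitors (adjusted p = 0.906) and 8 of 20 for astroglia and ependyma (adjusted p = 0.635). For tissues that could adhere to a dissected brain they numbered 7 of 22 for complement and liver plasma proteins (adjusted p = 0.635, with control array 4 apart at -0.24), 9 of 14 for endothelium (adjusted p = 0.810), 19 of 35 for skeletal muscle (adjusted p = 0.773), 18 of 41 for skin and keratins (adjusted p = 0.635) and 17 of 31 for retina and lens (adjusted p = 0.815). Housekeeping lists had 44 of 65 positive for ribosomal proteins (adjusted p = 0.635), 27 of 57 for oxidative phosphorylation (adjusted p = 0.906), 11 of 26 for glycolysis (adjusted p = 0.773) and 9 of 13 for cholesterol and fatty acid synthesis (adjusted p = 0.810). The remaining lists had 15 of 33 for insulin and growth factor signalling (adjusted p = 0.815), 18 of 37 for oxidative stress (adjusted p = 0.906), 44 of 91 for transcription and splicing (adjusted p = 0.635) and 37 of 60 for proteasome and ubiquitin (adjusted p = 0.635). The median of a list and camera's direction differed in sign in 5 lists and the mean in 2, all with camera p-values over 0.7.

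**Figure D2:**
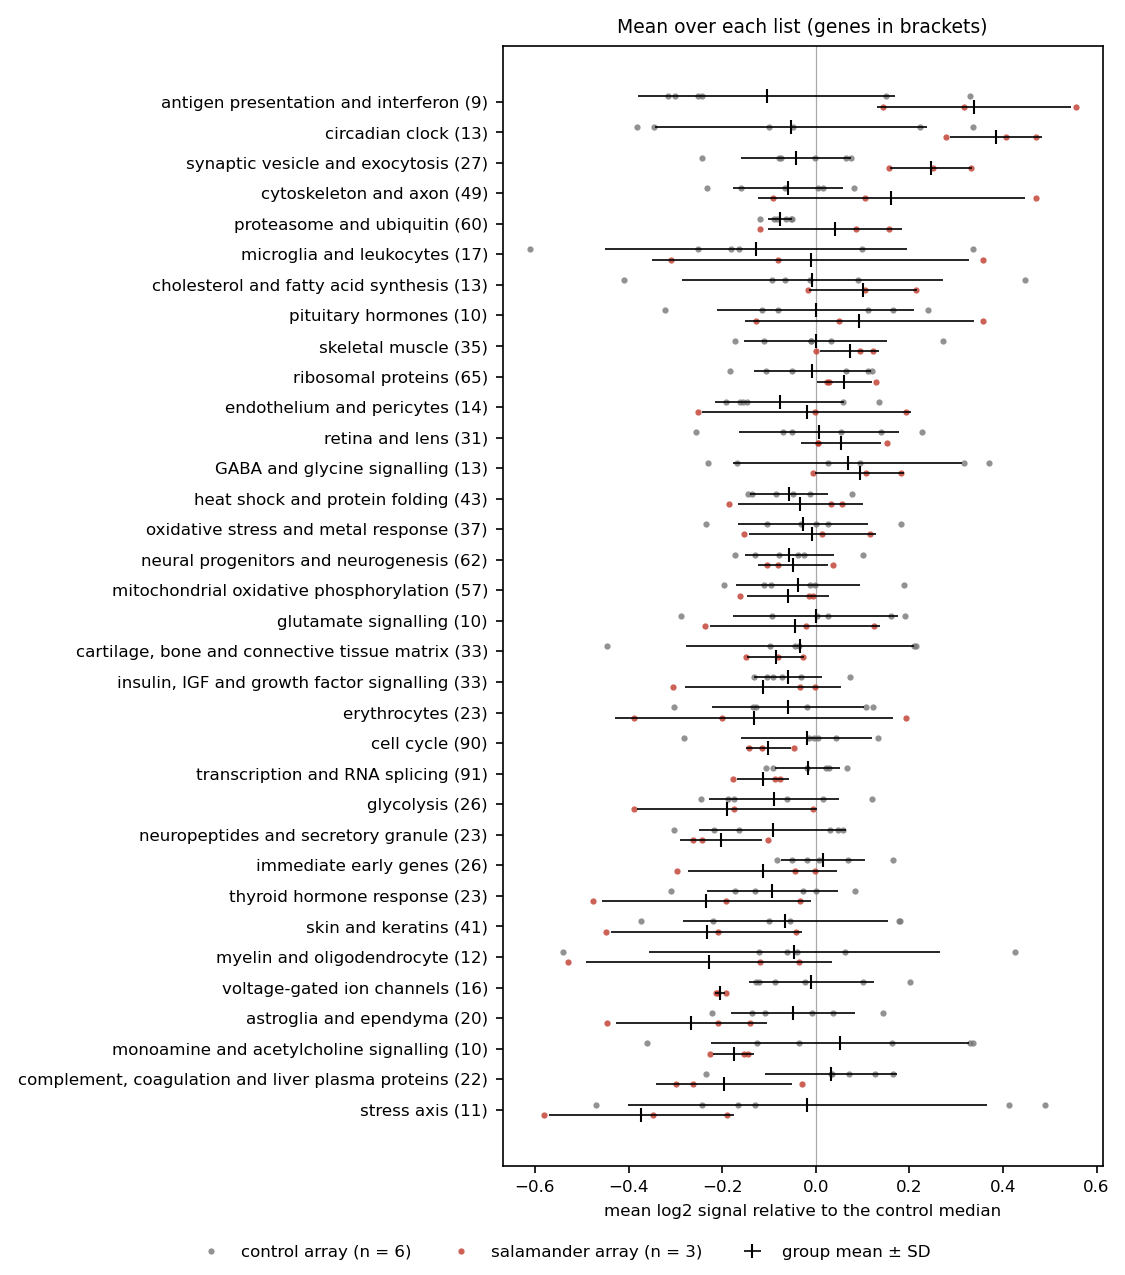
Mean log2 signal relative to the control median (horizontal axis) over the genes of each of the 34 lists, with control arrays in grey (n = 6), salamander arrays in red (n = 3), and ticks and bars for the group mean and SD. Lists are ordered by the difference between groups, from antigen presentation at 0.44 to the stress axis at -0.35, and none passes the adjusted threshold.

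Replicate spread differed between gene groups. Ribosomal protein genes had a median SD of 0.46 against 0.82 over all genes, and in 26 of 65 of them the interval excluded a 2-fold difference. Of 2000 random lists matched on probe sets per gene and on weak values, 0% had a median as low. The next lowest were pituitary hormones at 0.58, voltage-gated ion channels and the cytoskeleton and axon list at 0.61 each, which 16.6%, 17.5% and 10.1% of the matched lists reached, then proteasome and ubiquitin at 0.64 and monoamine and acetylcholine signalling at 0.65, which 0.15% and 0.2% reached.

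The poly-A spike-in RNAs separated the arrays into 2 sets that each held both groups. Their mean lay between 1.27 and 1.69 on controls 2, 3 and 4 and salamander 1 and 2. It lay between -2.25 and -1.76 on controls 1, 5 and 6 and salamander 3. The hybridization controls separated the same sets by less, at 0.069 to 0.374 on the former and -0.242 to -0.116 on the latter. With the poly-A spike-in level as a term, limma called 0 probe sets, 861 had an unadjusted p under 0.05, and camera called 0 lists. On the arrays with high spike-ins the numbers were 0, 856 and 0. On those with low spike-ins they were 0, 837 and 1, the list being cytoskeleton and axon (adjusted p = 0.0104, against 0.178 to 0.9997 in the other settings). That fit has 1 salamander array, which is assumed to vary as the controls do. Of the 52 genes named by rule, 44 had 1 sign in all 4 of these fits. The exceptions were cga, egr1, gh2, nr3c1, prl.1 and sst.1 of the 14 entries fixed in advance, and trhr and ncoa2 of the 38 others. Those 38 were picked for small p-values in these arrays, which favours 1 sign, so the count of 44 shows no stability. Sizes could still differ, as dnajc5 was at 2.84 on the high arrays and 0.055 on the low ones, and hba3 at -0.21 and -3.43. Of the lists, 19 of 34 had 1 sign in all 4 fits. The exceptions were the stress axis, pituitary hormones, GABA and glycine signalling, heat shock, ribosomal proteins, oxidative phosphorylation, cholesterol and fatty acid synthesis and myelin. Further exceptions were microglia and leukocytes, erythrocytes, endothelium, retina and lens, oxidative stress, cytoskeleton and axon, and proteasome and ubiquitin.

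**Figure D3:**
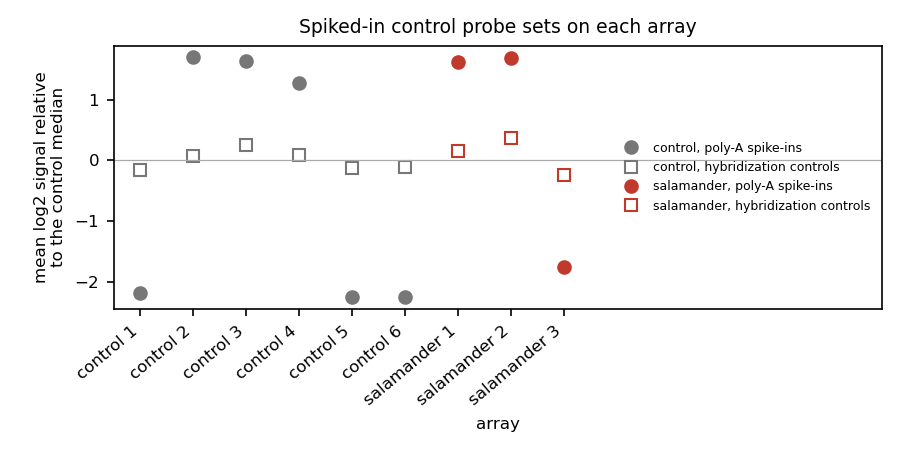
Mean log2 signal relative to the control median (vertical axis) of the poly-A spike-in probe sets (circles) and the hybridization control probe sets (squares) on each array, controls in grey and salamander arrays in red. The poly-A spike-ins lie above 1 on 5 arrays and below -1 on 4, and both groups occur at both levels.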

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

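The rules for the lower tail of the signals and for both array checks of the leading probe set were written before those tests. Even so, they used the bright set, the spike-in levels or the leading probe set, which were picked after the data were seen. The other tests below were chosen after the results were seen. No result differed between groups of a second factor, since the design has none, and the 3 salamander arrays were too few to be searched for a far-off array.

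Among the 6 controls, 1 array stood far from the rest in 6 of 90 sets of reported values, where chance gives about 4.5. Control 5 was at -0.79 for cwf19l1, with the other controls between -0.17 and 0.09. Control 1 was at 3.75 for gad1.2, with the others between -0.54 and 0.38. Control 4 was at -2.67 for col6a1, with the others between -0.13 and 0.22. Control 2 was at -1.11 for hsph1, with the others between -0.16 and 0.40. The mean of the cell cycle list was -0.28 on control 3 and between -0.01 and 0.13 on the others. The mean of the complement and liver plasma protein list was -0.24 on control 4 and between 0.03 and 0.16 on the others.

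No probe set passed the threshold. The 84 splits of the 9 arrays into 6 and 3 cannot speak on that count, since any split gives at least 0 calls; the highest other count was 1. Of these splits, 49 gave at least the real 798 probe sets at an unadjusted p under 0.05, up to 896, so chance cannot be excluded for that number. A spread over most probe sets added by the spike-in level is argued against, since with that level as a term the median residual SD fell from 0.96 to 0.94, or by 2.17%, where the other partitions of the arrays into 5 and 4 gave falls of 0.544% to 2.31% and 6 of the 126, this one included, gave one as large. Whether RNA levels that differ between pooled samples set the replicate spread stays open: deviations of bright probe sets of 1 gene correlated at 0.0090 on average over 1076 pairs, which decides nothing because no table shows that both probe sets of a pair report 1 frog transcript. Signals near background that hide changes remain open too: 356 of 7349 bright probe sets had an unadjusted p under 0.05, with 0 calls, and 38.0% of 4-fold changes simulated in the bright set were called, so moderate changes could be missed there too.

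Bright probe sets at an unadjusted p under 0.05 were lower with salamander larvae in 255 cases and higher in 101, a difference of 154. A longer lower tail of the log2 signals is consistent with part of it, since in 72.7% of bright probe sets the lowest deviation from the group median was larger than the highest, and the other splits all had more lower than higher, from 58 to 170 with a median of 113. A difference as large as the real one came from 4 of the 84 splits in the bright set, where both the set and the difference were picked after the data were seen, but over all probe sets the difference was 140 with 5 of the 84 splits reaching it, up to 180, and 14 reached the 255 lower bright probe sets, up to 282, while 3 had as few as the 101 higher ones, down to 98. The rule for these counts, written after the data were seen, asked for a share of splits under 0.05. The 4 splits for the bright difference and the 3 for the higher bright probe sets met it. The 5 and the 14 did not. In each count at least 1 other split went beyond the real value. As the counts that met the rule were among related ones looked at after the data were seen, chance is not taken as excluded. In the bright set the splits are also no even comparison. Its marks can come from the median of the real controls, so the set itself depends on the real grouping. Whether this favours probe sets lower with salamander larvae was not tested. Over all probe sets the lowest deviation was the larger in 57.5%. The highest other in the bright set, 170, set control 2 and salamander 1 and 2, all with high spike-ins, against the rest. It was also the split with 98 higher ones. That split kept 2 of the 3 salamander arrays together, so it holds part of the real contrast and is no clean measure of chance. With the spike-in level as a term the real difference was 146, and on the high spike-in arrays alone it was 132. An effect of the salamander larvae on the remainder was not tested apart from this and stays open.

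The unnamed probe set with the smallest p, chosen for that p, does not rest on 1 array, as its log2 difference was at least 3.22 without any of them, above the lower bound of its interval at 2.44. Nor does the spike-in level make the difference on these arrays, as it was 3.39 on the high arrays and 3.42 on the low ones. The latter value rests on salamander array 3 alone. A pick for the smallest p favours values that agree between arrays, so neither check tells how the difference would hold on other arrays. Chance remains open: 5 of the 84 splits had a smallest adjusted p no larger than the real 0.0846, the lowest of the others being 0.0037. Its weak control signals, its gene, and whether the probes bind a single frog transcript, stay open too.

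The real counts of called genes and called lists were also 0, on which the splits cannot speak either; the highest other counts were 2 genes and 1 list. At least 3 lists at a camera p under 0.05 appeared in 5 of the 84 splits, the real one included and 5 lists being the highest other, so chance cannot be excluded. One of those splits set controls 1, 5 and 6, all with low spike-ins, against the rest and gave 4 lists. With the spike-in level as a term the real split gave 3.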

How the results depend on the processing

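The bright set, the spike-in settings, the second quantile normalization and the unmoderated model were chosen after seeing the data. The count of called probe sets was 0 under each alternative that was run except the looser threshold of 0.10, which gave 1. Probe sets at an unadjusted p under 0.05 ranged from 778 to 842 when each array was left out. They numbered 475 after quantile normalization, of which 272 were lower, and 356 among the fewer bright probe sets. The fall to 475 comes from the centring on controls, which narrows the control arrays (interquartile range 0.904 to 1.002, salamander 1.32 to 1.34) although pairs of salamander arrays differed with an SD of 1.44 to 1.45 and pairs of controls with 1.39 to 1.48. With each probe set first centred on the mean of all 9 arrays, the ranges were 1.19 to 1.27 and 1.22 to 1.23, and quantile normalization gave 804 probe sets, 0 calls, 517 genes with 2-fold excluded and 3 lists at a camera p under 0.05. Limits of 0, 1 and 2 marked values for a bright probe set were tried, and gave 4521, 7349 and 9778 probe sets with 0 calls each. Called genes were 0 except without control 3, where trappc6a passed at 3.999 (adjusted p = 0.0150 in limma), against 3.31 (SE 0.88, adjusted p = 0.687) with all arrays and adjusted p-values of 0.380 to 0.9998 in the other settings; leaving out arrays gave 0 to 1 called genes. Trappc6a was named after its values were seen.

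Genes whose interval excluded 2-fold, 516 with all arrays, depend on the number of arrays. They were 71 to 363 with 1 array left out, 2 with controls 1 to 3, 10 with controls 4 to 6, 0 at either spike-in level and 894 without moderation; the spike-in term left 398. Lists at a camera p under 0.05, 3 with all arrays, were 0 to 3 with 1 array left out (0 without salamander 3 and 1 without salamander 2), and 1 each with controls 1 to 3, high spike-ins only and an estimated correlation. Called lists were 0 throughout except 1 on the low spike-in arrays.

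Same-numbered arrays deviated from their group means with correlations of 0.0059, 0.016 and -0.0049 for numbers 1 to 3, and only salamander 2 correlated best with its own number. These correlations show no pairing by number. They cannot exclude one, since deviations of different probe sets of 1 gene also correlated at only 0.0088 on average. The replicate block over arrays 1 to 3 of each group gave 0 called probe sets, 828 at an unadjusted p under 0.05, 0 called genes, 0 genes with 2-fold excluded, 0 called lists and 1 list at a camera p under 0.05, against 882 probe sets at that p for the same 6 arrays without the block.

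No named gene passed in any alternative. Of 52, 42 kept their sign throughout, and of 34 lists 12 did. Of the 52 genes, 38 were picked for small p-values in these arrays, which favours a kept sign, so the count of 42 shows no stability. Signs that changed with a shift over 1 SD were, on high spike-in arrays, cga at 0.41, the stress axis mean at 0.024 and the cytoskeleton mean at -0.027; on low spike-in arrays, nr3c1 at -0.67, sst.1 at 0.74, ncoa2 at 0.053 and the proteasome mean at -0.040; and among bright probe sets, the pituitary mean at -0.26 and the insulin and growth factor mean at 0.085. The cause was not tested. Not run, for want of an absolute level, were the upper-quarter filter, the pseudocount, the intensity trend and the trend with robust hyperparameters; robust eBayes without trend gave 758 probe sets at an unadjusted p under 0.05.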

Other observations

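The comparison of probe sets of 1 gene was chosen after the data were seen. The 4219 pairs were of probe sets that carry the same gene symbol, homeologs included. In 115 of them, in which both probe sets had a replicate SD under 0.5, the differences between groups had the same sign in 60.0% and the deviations from group means correlated at 0.043, against 49.9% and 0.0088 over all of the pairs. Pairs of homeologs and pairs for 1 transcript were not told apart. Over all of the pairs, the replicate SD of the probe sets correlated with a Spearman rho of 0.074 and the number of weak values with one of 0.10, against 0.0088 and -0.0033 in random pairs. The deviations of poly-A spike-in probe sets, which follow RNA added to the samples, correlated at 0.820 on average. Between control arrays the deviations correlated at -0.22 to -0.17, where removing the mean of 6 arrays gives -0.2 by itself.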
